A study of Rattus norvegicus with 12 samples.

How the data were processed

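Placental chorionic tissue of 6 normal pregnant control rats and 6 RUPP rats was analysed on Affymetrix rat Gene 1.0 ST arrays, 1 array per sample. Per the labels' protocols, total RNA was isolated with TRIzol and a PureLink kit and labelled with biotin. Groups and replicate numbers were taken from the sample titles, and the series design text names 6 rats per group. Whether the RNA of a rat came from 1 placenta or several is not given in the sources used here.

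The deposited table holds log2 expression values made by the authors with Affymetrix Expression Console, per the submitters' processing notes. The version, the summarization method and the normalization setting are not given in the sources used here. The log2 scale was read from the values, which run from 2.04 to 14.7, with array medians between 7.89 and 7.95. The centring of the arrays by the authors is therefore unknown beyond these medians. No array carried the same values as another.

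Of 29214 probe sets, 15310 had exactly 1 gene symbol in the platform annotation table used here, 323 had several, and 13581 were unnamed here. Entrez identifiers of 15279 probe sets matched the current rat gene table, and 0 symbols changed. Only probe sets with 1 symbol entered the gene tests, and for the 527 genes with several the probe set with the highest mean over all 12 arrays stood for the gene, which left 14506 genes. No filter on dim probe sets was applied and no renormalization was done. Positions in the genome were not used.

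RUPP was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided, 12 arrays, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Positive log2 fold changes mean higher in RUPP. The 95% confidence intervals come from the same model. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members. A list of fetal sex genes had 1 measured member and was not tested. Camera with an estimated correlation, the directional test fry, and an exact permutation test of list scores over all 924 assignments of 6 against 6 arrays were set beside it. The score of a list on an array is the mean deviation of its members from their own means over the 12 arrays.

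The lists, the limma, camera and fry tests and the rule for named genes were fixed before the data were examined, and the exact permutation test of list scores was added afterwards. The rule took the 12 genes with the smallest p in each direction where fewer passed the adjusted threshold, leaving out symbols that are locus numbers, 12 genes fixed by name, and for each list up to 4 members with the smallest p. Genes outside the rule are said to have been chosen after their values were seen.

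The alternatives were quantile normalization, subtraction of array medians, filters at the 25th and 50th percentile of mean level, testing each probe set, the mean of all probe sets of a gene, a trended and robust fit, array weights, blocks for the replicate number and for the series of description numbers, fits within each series, leaving out each array, and other thresholds. The effects of these settings are given in the closing section. The fit was tested on simulated data with 200 changed genes among 14506 in 10 runs, where 51.6%, 95.8% and 99.2% of genes changed 1.2-fold, 1.5-fold and 2-fold were recovered. Camera, tested in 20 simulated runs with 1 list shifted by 0.15, called that list in 20 of 20 runs; genes were independent in these simulations, unlike real genes of a tissue. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.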

Results

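Gene expression was measured in placental chorionic tissue of pregnant Sprague Dawley rats, with 1 array for each of 6 control rats and 6 rats with reduced uterine perfusion pressure (RUPP). In the RUPP model, blood flow to the pregnant uterus is restricted by surgery, here on gestational day 14, and tissue was collected on day 19 after 5 days of ischemia. Controls were normal pregnant rats, and their day of collection is not given in the labels, so a difference in gestational day between the groups was not ruled out for any comparison below. No operation is given for the controls either, so effects of surgery itself were not separated from those of reduced perfusion. The comparison asks which placental genes differ after placental ischemia, a condition used in rats as a model of preeclampsia. Median log2 signal over all 29214 probe sets lay between 7.89 and 7.95 on the 12 arrays, and any pair of arrays correlated at r = 0.994 to 0.997 across probe sets. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.06, with a median within-group SD of 0.10 (n = 6 per group).

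No single gene differed between RUPP and control placentas at an adjusted p under 0.05 (limma, 14506 genes, smallest adjusted p = 0.241). Most differences were small, and the 95% confidence interval lay inside a 1.5-fold change either way for 14273 genes (98.4%) and inside a 1.2-fold change for 11606. At an unadjusted p under 0.05 there were 1704 genes, 721 higher and 983 lower in RUPP, where 725 would be expected by chance. With array medians subtracted, the 1756 genes at this level divided into 1285 higher and 471 lower. The balance of small increases and decreases thus depends on the centring of the arrays. It also varied with signal. Among the 7253 genes above the median level, 244 were higher and 769 lower at an unadjusted p under 0.05. The median log2 fold change of those brighter genes was -0.02, against -0.009 over all genes. Whether this reflects expression or the scaling of the arrays was not tested. In simulated data of this size with 200 changed genes and independent noise, 51.6% of 1.2-fold changes and 95.8% of 1.5-fold changes were recovered. These rates may not hold for the genes with the largest differences here. Their standard errors were above the median of 0.06, such as 0.39 for Prl7a3, 0.28 for Mmp12 and 0.16 for Prl8a4. The count of 0 higher genes rested on control 5: without that array, 15 genes were higher in RUPP and 0 lower. Without RUPP 6, 1 gene was lower, Bmp8a, a bone morphogenetic protein (log2 fold change -0.46, adjusted p = 0.0344, limma), and 0 were higher. Bmp8a is named after its values were seen.

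The 15 genes that were higher once control 5 was left out included 8 genes of the expanded rodent prolactin family. These were Prl8a5, Prl8a4, Prl8a7, Prl8a9, Prl8a2 (of the decidual list described below), Prl8a3, Prl4a1 and Prl3d4. The others were the pregnancy-specific glycoprotein gene Psg19, the potassium channel gene Kcnh1, the circadian repressor gene Bhlhe41, the prostaglandin-degrading enzyme gene Hpgd, the serotonin receptor gene Htr1d, Taf7l and Sslp1l1. Of the 15, 7 belong to the junctional zone list described below. Their log2 fold changes without control 5 included 0.98 for Taf7l, 0.95 for Prl8a3, 0.82 for Prl8a4, 0.53 for Kcnh1 and 0.40 for Bhlhe41. These genes are named because of this result and, except for those also named elsewhere, were chosen after their values were seen.

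Among the 12 genes with the smallest p and a higher mean in RUPP, none passed the adjusted threshold (adjusted p = 0.241 for each, limma). Bhlhe41 (probe set 10867026) had a log2 level of 9.83 ± 0.13 (SD, n = 6) in control and 10.18 ± 0.08 in RUPP, a log2 difference of 0.35 (95% CI 0.22 to 0.48). Fosl1 (probe set 10713045), which encodes the AP-1 transcription factor subunit Fra-1, differed by 0.57 (95% CI 0.32 to 0.83). Kcnh1 differed by 0.44 (0.24 to 0.64). Cited2, which encodes a co-regulator that restrains hypoxia-inducible factor, differed by 0.32 (0.17 to 0.47). The Wnt receptor gene Ror2 differed by 0.21, the ubiquitin-conjugating enzyme gene Ube2t by 0.21 and the chemokine receptor gene Cxcr6 by 0.25. Igbp1b differed by 0.35, and Polr1has, Plcd4, Prxl2b and the phosphatase gene Ptpro by 0.21 to 0.23. Igbp1b, Ube2t, Polr1has, Plcd4, Cxcr6 and Ptpro were dim, with control means of 6.53 to 6.74. The lower quartiles of the arrays were 6.47 to 6.56. All 6 RUPP arrays lay above the control median for each of these 12 genes, and for 10 of them the groups did not overlap.

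The 12 genes with the smallest p and a lower mean in RUPP had an adjusted p of 0.241 each as well (limma). Tarbp2 (probe set 10940463), which encodes a partner of Dicer, had a log2 level of 9.91 ± 0.03 (SD, n = 6) in control and 9.73 ± 0.05 in RUPP. The log2 difference was -0.19 (95% CI -0.26 to -0.11). Tarbp2 has 2 probe sets, of which the brighter was used. Its difference was -0.20 to -0.18 when single arrays were left out, but fell to -0.09 at the weakest over all alternatives. Blvra, the biliverdin reductase gene that acts after heme oxygenase, differed by -0.30 (-0.44 to -0.16), and Slco4c1, an organic anion transporter gene, by -0.29 (-0.43 to -0.15). Pkia, an inhibitor of protein kinase A, differed by -0.26, the dipeptidase gene Dpep1 by -0.26 and Olfml1 by -0.35. Hook1, Slc35f2, Tmem184a, Zfp382, Mok and Eogt differed by -0.26 to -0.16. For 9 of these 12 genes the groups did not overlap. Over all genes, 101 had groups that did not overlap (41 higher, 60 lower), or 0.696%, where chance alone gives 0.216%, about 31 genes.

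**Figure D1:**
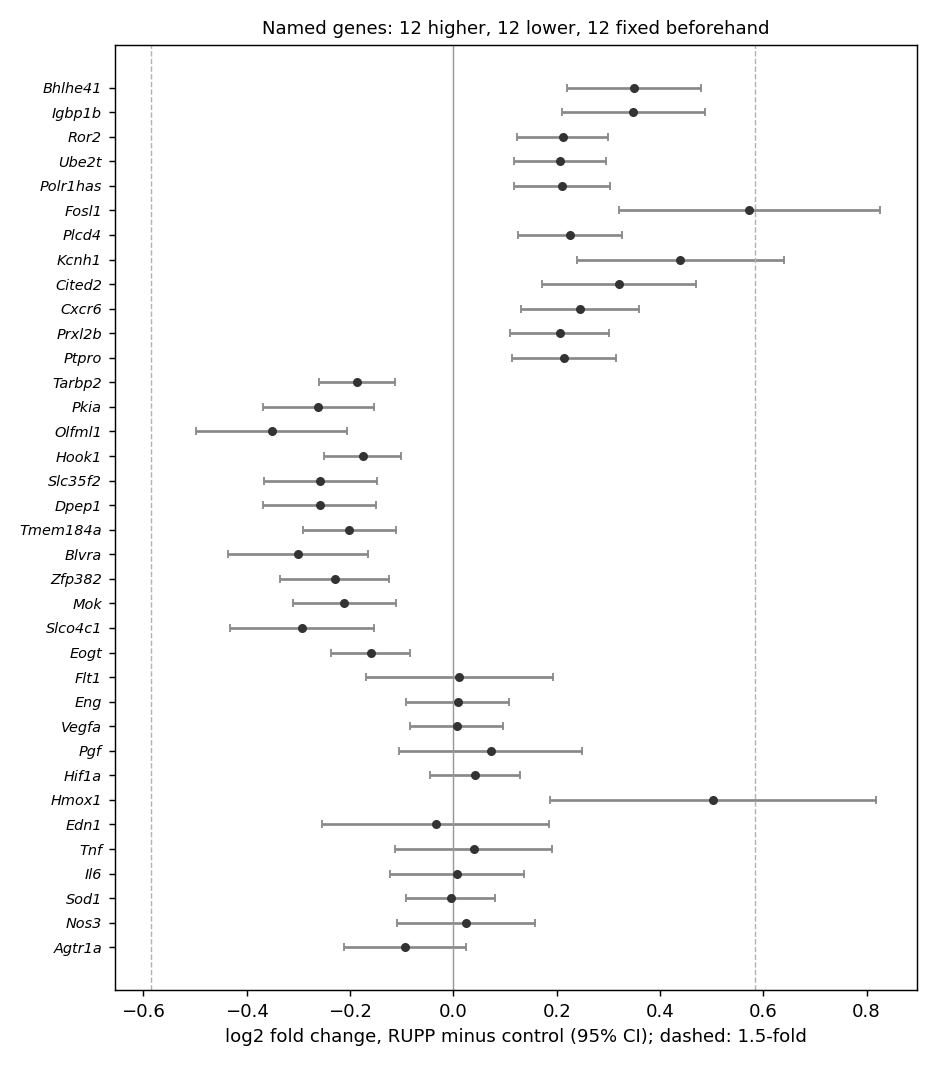
Log2 fold change of RUPP over control (horizontal axis) for the 12 genes with the smallest p in each direction and the 12 genes fixed before the data were examined. Points are differences of group means (n = 6 per group), bars are 95% confidence intervals and dashed lines mark a 1.5-fold change; Hmox1 at 0.50 stands apart from the other fixed genes.

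Placental hormone genes had several of the largest fold changes, none past the adjusted threshold. In all, 18 genes were over 1.5-fold higher and 1 lower in RUPP, whatever their p. Only Prl7a3 exceeded 2-fold, at 2.58-fold (log2 difference 1.37, 95% CI 0.52 to 2.21, adjusted p = 0.283, limma). A 1.5-fold difference with an unadjusted p under 0.05 was found for 15 genes, all higher in RUPP. Of these, 10 were prolactin-family or pregnancy-specific glycoprotein genes: Prl7a3, Prl5a1, Prl8a3, Prl3d4, Prl6a1, Prl8a4, Prl5a2, Prl8a2, Psg19 and Prl8a9. The other 5 were Mmp12, the macrophage elastase gene, at a log2 difference of 0.97, the carcinoembryonic-antigen-family gene Cgm4 at 0.92, Taf7l at 0.78, the placental cathepsin gene Ctsm at 0.67 and Htr1d at 0.60. Prl7a3 was chosen after its values were seen, as were the members of this group not named by the fixed rule.

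Of 30 gene lists fixed before the data were examined, 29 had at least 5 measured members and were tested with camera. With the preset inter-gene correlation of 0.01, 2 lists were higher and 2 lower in RUPP at an adjusted p under 0.05. With a correlation estimated from the data, 0 lists were called in either direction, and the directional test fry and an exact permutation test of the array scores also called 0. The non-directional form of fry, which gives no sign, passed immediate early genes (adjusted p = 0.00761). It also passed the junctional zone and smooth muscle lists (adjusted p = 0.0288 each). The number of lists called by camera depended on single arrays. Without control 3 there were 6 higher lists, without RUPP 3 there were 5, and without control 4, control 5, RUPP 4 or RUPP 5 there were 4 each. Without control 4 or RUPP 4 there were 5 lower lists each. Leaving out control 2, control 3 and RUPP 4 together, the arrays farthest out on the first principal components, gave 7 higher and 4 lower lists with 0 genes past the threshold, a check chosen after the data were seen. With an estimated correlation, 0 of 664 list values passed in any of 23 alternative fits, those without single arrays included (smallest adjusted p = 0.0847, the junctional zone list without control 5). Calls given below for such fits are camera calls at the preset correlation, and each is lost with an estimated one.

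The junctional zone and giant cell trophoblast list, made of hormone and marker genes of the endocrine layer of the rat placenta, was higher in RUPP (camera adjusted p = 3.69e-11, adjusted p = 0.553 with an estimated correlation). Its array score was -0.19 ± 0.24 (SD, n = 6) in control and 0.19 ± 0.16 in RUPP, a mean log2 difference of 0.38. Of 26 measured members, 22 had a fold change above 0 and 14 passed when adjusted over the list alone, all higher, against 0 over all genes tested. The members with the smallest p were Prl8a5 (0.50), Prl8a4 (0.67), Prl8a9 (0.62) and Prl8a7 (0.51), placental prolactin-family hormones. Prl5a1 differed by 0.84, Prl3d4 by 0.74, Psg19 by 0.62 and the spongiotrophoblast marker Tpbpa by 0.22. The brightest members showed little difference: Prl3b1, the placental lactogen II gene, stood at a log2 level of 14.13 in control and 14.12 in RUPP, Prl2a1 differed by 0.05 and Prl2b1 by 0.05. Prl5a1, Prl3d4, Psg19, Tpbpa, Prl3b1, Prl2a1 and Prl2b1 were picked after their values were seen.

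The exact two-sided permutation p of the junctional zone score was 0.0130, and 0.126 after adjustment over the 29 lists. Control 5 scored 0.29, among the RUPP arrays (0.02 to 0.40), while the other controls lay at -0.22 or lower. Without control 5 the mean difference was 0.47. The sample descriptions end in numbers whose meaning is not stated. Among arrays with numbers up to 18 (4 per group) the difference was 0.37, and among those with numbers from 19 (2 per group) it was 0.40. The part from 19 holds control 5, which scored above RUPP 2 (0.27), so its difference rests on the low score of control 6 (-0.42). The division between 18 and 19 was made here, with no gap in the numbers. Within each part the controls come first (9 to 12 before 14 to 18, and 19 to 20 before 24 to 25). If the numbers follow a processing order, agreement between the parts cannot separate group from order, here or for other lists.

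**Figure D2:**
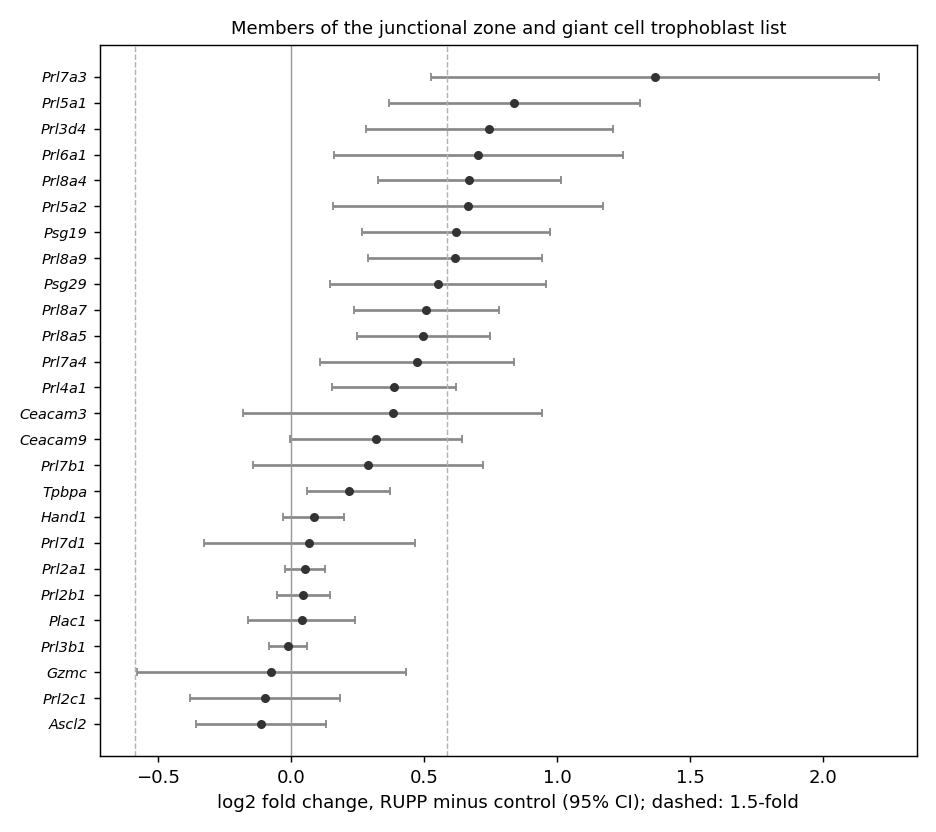
Log2 fold change of RUPP over control (horizontal axis) for the 26 measured members of the junctional zone and giant cell trophoblast list. Points are differences of group means (n = 6 per group), bars are 95% confidence intervals and dashed lines mark a 1.5-fold change; 22 members lie above 0, with Prl7a3 at 1.37 and Prl3b1 at -0.01.

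Other trophoblast and maternal tissue markers did not pass the test. The labyrinth trophoblast list, from the exchange layer of the placenta, had a mean log2 difference of -0.004 (camera adjusted p = 0.983; -0.02 without RUPP 2 to 0.02 without RUPP 4), with Tfap2c at 0.19, Cldn4 at 0.22, the syncytin-type gene Ervfrd-1 at -0.20 and Epcam at 0.07. Decidual and endometrial stroma markers had a mean difference of 0.03 (adjusted p = 0.983), which ranged from 0.01 without RUPP 4 to 0.05 without control 2. Of these, Prl8a2, a decidual prolactin-family gene, was 0.63 higher and passed when adjusted over the list alone, while the progesterone receptor gene Pgr stood at -0.14, Prlr at -0.13 and Wnt4 at 0.10. Placental growth genes with imprinted expression had a mean difference of -0.01 (adjusted p = 0.894), a mean that ran from -0.02 without control 4 to 0.01 without RUPP 6, led by Slc22a18 at -0.14, Zim1 at 0.10, Grb10 at -0.07 and Tfpi2 at -0.11.

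Smooth muscle markers were lower in RUPP (camera adjusted p = 0.000171, adjusted p = 0.553 with an estimated correlation). All 13 measured members had a fold change below 0, with a mean log2 difference of -0.15, and 2 passed when adjusted over the list alone. These were the calcium-storage gene Casq2 (-0.34) and the myosin light chain kinase gene Mylk (-0.25). The actin-binding protein gene Tagln stood at -0.30 and phospholamban, Pln, at -0.20. Casq2 and Pln were dim, with control means of 7.09 and 6.95, and both level filters removed them. Above the 25th percentile of level the list mean was -0.13 (camera adjusted p = 0.0122). The array score was 0.07 ± 0.04 (SD, n = 6) in control and -0.07 ± 0.09 in RUPP, with an exact two-sided permutation p of 0.00433, or 0.126 adjusted over the 29 lists. The difference was -0.11 among arrays with description numbers up to 18 and -0.23 among the rest. Fibroblast and extracellular matrix genes had a mean difference of -0.08 and did not pass (adjusted p = 0.200), with osteoglycin, Ogn, at -0.58, the collagen cross-linking enzyme gene Lox at -0.32, Pdgfrb at 0.09 and Col5a2 at -0.11.

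Oxidative phosphorylation genes, which encode subunits of the mitochondrial respiratory chain and ATP synthase, were lower in RUPP by a small amount (camera adjusted p = 3.31e-05, adjusted p = 0.553 with an estimated correlation). The mean log2 difference was -0.07, with 32 of 34 measured members below 0 and 0 past the threshold adjusted over the list alone. The members with the smallest p were Ndufb8 of complex I (-0.21), Cox5b of complex IV (-0.14), Sdha of complex II (-0.11) and Atp5po of the ATP synthase (-0.17). Scores were 0.04 ± 0.04 (SD, n = 6) in control and -0.04 ± 0.05 in RUPP, with an exact permutation p of 0.0195, or 0.141 adjusted. The difference was -0.09 among arrays with description numbers up to 18 and -0.04 among the 4 arrays with higher numbers, where the list no longer passed (camera adjusted p = 0.292). Without control 2, control 3 and RUPP 4, which had the lowest score (-0.11), it was -0.04 (camera adjusted p = 0.0219). Among genes above the median level it was -0.07 (camera adjusted p = 0.00470), and after quantile normalization -0.06 (camera adjusted p = 4.36e-05). Glycolysis genes had a mean difference of 0.01 (adjusted p = 0.933; 0.002 without RUPP 4 to 0.02 without control 1), with Aldoc at 0.28, Pkm at -0.09, the lactate exporter gene Slc16a3 at -0.07 and Tpi1 at 0.06.

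Neutrophil markers were higher in RUPP (camera adjusted p = 0.00144, adjusted p = 0.553 with an estimated correlation). Of 14 measured members, 12 had a fold change above 0, with a mean log2 difference of 0.20, and 0 passed when adjusted over the list alone. The colony-stimulating factor receptor gene Csf3r differed by 0.28, the defensin gene Defa5 by 0.25, the calgranulin gene S100a9 by 0.57 and the chemokine receptor gene Cxcr2 by 0.28. The members were dim, with mean levels from 6.01 (S100a8) to 8.61 (S100a9), and too few lay above the median level for a test there. Above the 25th percentile of level the mean difference was 0.29 (camera adjusted p = 0.00157). Whether the variation of increases and decreases with signal contributes was not tested. Scores spread widely, -0.10 ± 0.28 (SD, n = 6) in control and 0.10 ± 0.18 in RUPP, with the highest score, 0.43, in control 3 (exact permutation p = 0.169, adjusted 0.445). Without control 3 the mean difference was 0.31, and without the 3 outlying arrays 0.32. After quantile normalization it was 0.18 (camera adjusted p = 0.0148). The difference was 0.16 and 0.28 in the lower and higher description numbers. Erythroid genes, carried by red blood cells, had a mean difference of -0.14 (camera adjusted p = 0.110), and they were lower at -0.28 without RUPP 4, the array with the highest erythroid score of 0.62 (camera adjusted p = 1.93e-07, adjusted p = 0.632 with an estimated correlation). Without control 1 or control 4 the preset test also passed, at -0.18 each (adjusted p = 0.738 and 0.758 with an estimated correlation), while the difference shrank to -0.07 without RUPP 1 (adjusted p = 0.585), to -0.07 without control 2 and to -0.09 without RUPP 2. It was 0.01 among description numbers up to 18 and -0.44 from 19. The erythroid members with the smallest p were Sptb (-0.35), Hbb (-0.10), Hbb-b1 (-0.12) and Rhd (-0.41).

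Macrophage markers had a mean difference of 0.09 and did not pass (camera adjusted p = 0.0532, adjusted p = 0.685 with an estimated correlation), with Cd68 at 0.27, lysozyme, Lyz2, at 0.56, Cd53 at 0.25 and Csf1r at -0.10. Without control 2, control 3, control 4, RUPP 2 or RUPP 3 this list passed the preset test, with a mean difference of 0.10 to 0.12, and without control 6 the difference was 0.06. It also passed after quantile normalization, in both level filters and with the yolk sac score as a covariate (0.09 to 0.11). T and NK cell markers averaged 0.02 (adjusted p = 0.123), with Ncr1 at 0.13, Il2rb at 0.14, Cd3e at 0.12 and the granzyme gene Gzmb at -0.30, and ranged from 0.01 without control 5 to 0.04 without RUPP 4, where it passed. The T and NK mean was 0.10 from description number 19 (camera adjusted p = 0.000575). Its sign turned in 2 alternatives, with a lowest value of -0.02. Inflammatory cytokines and adhesion molecules averaged 0.05 (adjusted p = 0.175), with the chemokine gene Ccl2 at 0.33, Ccl5 at 0.10, the adhesion molecule gene Icam1 at -0.35 and Il1r1 at -0.14, and ranged from 0.03 without RUPP 1 to 0.08 without control 3, where it passed. From description number 19 the inflammatory mean was 0.17 (camera adjusted p = 5.52e-05), while its lowest value over all alternatives was -0.01. Complement and coagulation genes averaged 0.05 (adjusted p = 0.0807), with Cfd at 0.15, the urokinase gene Plau at 0.35, Tfpi2 at -0.11 and Tfpi at 0.07, and passed without control 3 (0.06) or RUPP 3 (0.07), while the mean was 0.02 without RUPP 4. Interferon-stimulated genes averaged -0.07 (adjusted p = 0.200), with the RNA sensor gene Ifih1 at -0.29, Ifi27 at -0.18, Irf9 at -0.17 and Bst2 at -0.18, and passed at -0.11 without control 4 or without RUPP 4, while the mean was -0.03 without RUPP 2 (adjusted p = 0.819). The interferon list also passed with array weights (-0.11), without the 3 outlying arrays (-0.10) and from description number 19 (-0.17). Its highest value over all alternatives was -0.02. Matrix proteases and their inhibitors averaged 0.10 (adjusted p = 0.182), with Mmp12 at 0.97, Plau at 0.35, Mmp1 at 0.49 and Mmp3 at 0.20.

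Hypoxia-inducible genes showed no shift past the test after 5 days of reduced perfusion, and 13 of 27 measured members were above 0, with a mean log2 difference of -0.01 ± 0.03 (SE, n = 6 per group; camera adjusted p = 0.983). The members with the smallest p were the prolyl hydroxylase gene Egln1 (-0.10), P4ha2 (0.13), Ero1a (0.09) and Angptl4 (-0.10). Hif1a, the oxygen-regulated transcription factor gene, differed by 0.04 (95% CI -0.04 to 0.13). Angiogenic factors and receptors had a mean difference of -0.02 (adjusted p = 0.933), led by Angpt1 at -0.31, Sema3f at 0.09, Nrp1 at -0.10 and Apln at -0.14. The preeclampsia-related genes of this list had mean differences close to 0 over all 12 arrays. Flt1, which encodes the VEGF receptor with a soluble form, differed by 0.01 (95% CI -0.17 to 0.19), Eng, endoglin, by 0.01 (-0.09 to 0.11), Vegfa by 0.01 (-0.08 to 0.10) and Pgf, placental growth factor, by 0.07 (-0.10 to 0.25). The sign of Flt1, Eng and Vegfa turned between alternatives: among description numbers up to 18 they stood at 0.13, 0.08 and 0.04, and from 19 at -0.22, -0.13 and -0.06, none past the adjusted threshold. The 1 probe set used for Flt1 does not separate the soluble from the membrane-bound transcript here. RUPP 4 stood above the other RUPP arrays in both lists, at 0.13 for hypoxia-inducible and 0.08 for angiogenic genes. Without it the mean differences were -0.03 (camera adjusted p = 0.241) and -0.04 (adjusted p = 0.377). Over all leave-one-out fits they reached 0.01 without RUPP 2 and -0.01 without control 1.

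Vasoactive genes had a mean difference of 0.03 (camera adjusted p = 0.200), with the prostacyclin receptor gene Ptgir at 0.17, the prostacyclin synthase gene Ptgis at 0.16, the bradykinin receptor gene Bdkrb2 at 0.15 and Nos2 at 0.12. Their mean ranged from 0.01 without RUPP 4 to 0.05 without control 2. Over all alternatives it ran from -0.06 to 0.07, with 1 change of sign. Edn1, the endothelin-1 gene, differed by -0.03 (95% CI -0.25 to 0.19), Nos3 by 0.02 (-0.11 to 0.16) and Agtr1a, an angiotensin II receptor gene, by -0.09 (-0.21 to 0.03). The cytokine genes Tnf and Il6 differed by 0.04 (-0.11 to 0.19) and 0.01 (-0.12 to 0.14). Antioxidant and oxidant enzymes averaged -0.02 (adjusted p = 0.798), with Gpx2 at -0.28, Gpx4 at -0.14 and the metallothionein gene Mt2A at 0.16, and the mean ranged from -0.04 without control 4 to 0.01 without control 2. Sod1 differed by -0.01 (-0.09 to 0.08). Hmox1, heme oxygenase 1, had the largest difference of the 12 genes fixed beforehand: 8.90 ± 0.25 (SD, n = 6) in control against 9.40 ± 0.32 in RUPP, a log2 difference of 0.50 (95% CI 0.19 to 0.82) that did not pass (adjusted p = 0.284, limma), with 6 of 6 RUPP arrays above the control median.

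Immediate early genes had a mean difference of 0.06 (camera adjusted p = 0.0532), with Junb at 0.15, Klf4 at 0.11 and Klf2 at -0.17, and Fosl1 (0.57) was the 1 member past the threshold adjusted over the list alone. This list passed without control 3, control 4, control 5, RUPP 3, RUPP 4 or RUPP 5, with a mean difference of 0.06 to 0.08, and also after quantile normalization and in both level filters (adjusted p = 0.618 with an estimated correlation on all arrays). Cholesterol synthesis genes averaged -0.07 (adjusted p = 0.0532), with Lss at -0.15, Idi1 at -0.15, Mvk at -0.13 and Srebf2 at -0.18, and passed without control 4, control 5, RUPP 4, RUPP 5 or RUPP 6, at -0.11 to -0.06, and also with array weights and with ranks (adjusted p = 0.685 with an estimated correlation on all arrays). Cell cycle genes averaged 0.01 (adjusted p = 0.182), with Ccne1, cyclin E1, 0.37 lower on the log2 scale and past the threshold adjusted over the list alone, Kif20a at -0.36, Mcm7 at 0.15 and Aurkb at 0.21. The list passed without control 1 (0.04) or RUPP 5 (0.03), and its sign turned without control 4 (-0.01). Genes of p53 and apoptosis averaged -0.04 (adjusted p = 0.798), with the cell cycle inhibitor gene Cdkn1a at -0.35, Sesn1 at -0.17, Aen at 0.10 and Tp53inp1 at 0.16. The exact permutation p of the p53 score was 0.0108, or 0.126 adjusted. That is below the unadjusted 0.0130 of the junctional zone list, so this test does not single out the lists called by camera. Unfolded protein response genes averaged 0.03 (adjusted p = 0.175), with Herpud1 at 0.18, Xbp1 at 0.11, Atf4 at 0.11 and Atf3 at -0.15, and ranged from 0.01 without RUPP 6 to 0.05 without control 5, where it passed. Steroid hormone synthesis genes averaged -0.003 (adjusted p = 0.992; -0.02 without RUPP 1 to 0.02 without RUPP 4), with Hsd17b7 at -0.16, the side-chain cleavage enzyme gene Cyp11a1 at 0.15, Star at -0.29 and Hsd3b2 at 0.20. Nutrient transporters averaged -0.03 (adjusted p = 0.200), with Slc22a3 at -0.16, Slc7a7 at -0.18, the endothelial lipase gene Lipg at -0.12 and Slc27a4 at -0.15.

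Endothelial markers averaged 0.03 (camera adjusted p = 0.316), with Sox7 at 0.16, Esam at 0.10, Cldn5 at 0.15 and Sox18 at 0.09. The sign rested on RUPP 4, without which the mean was -0.02. Among description numbers up to 18 the mean was 0.08 (camera adjusted p = 0.0374, adjusted p = 0.996 with an estimated correlation), and from 19 it was -0.08 (camera adjusted p = 0.0351, adjusted p = 0.529 with an estimated correlation). The difference between these values was not tested. Yolk sac endoderm markers averaged -0.08 (adjusted p = 0.992), with Lgmn at 0.05, Apoa2 at -0.46, Dab2 at -0.06 and Cubn at -0.51, none past the threshold. The sign of this difference turned with single arrays, from -0.31 without control 6 to 0.25 without control 2, and it was also above 0 without control 3 (0.18), RUPP 1 (0.12) or RUPP 3 (0.01). Without control 2, control 3 and RUPP 4, a set that holds both highest-scoring controls, the difference was 0.60 (camera adjusted p = 1.51e-06, adjusted p = 0.463 with an estimated correlation). Among description numbers from 19 it was 0.25 (camera adjusted p = 0.00171, adjusted p = 0.509 with an estimated correlation), against -0.24 up to 18. Their array score ranged from -1.13 in control 6 to 1.66 in control 2, with an SD of 1.21 in control and 0.71 in RUPP. With this score as a covariate, a check chosen after the data were seen, the junctional zone difference was 0.38 and the neutrophil difference 0.21. Median, mean and camera direction did not share a sign for the glycolysis, angiogenic, decidual, imprinted, labyrinth and steroid lists, all close to 0.

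**Figure D3:**
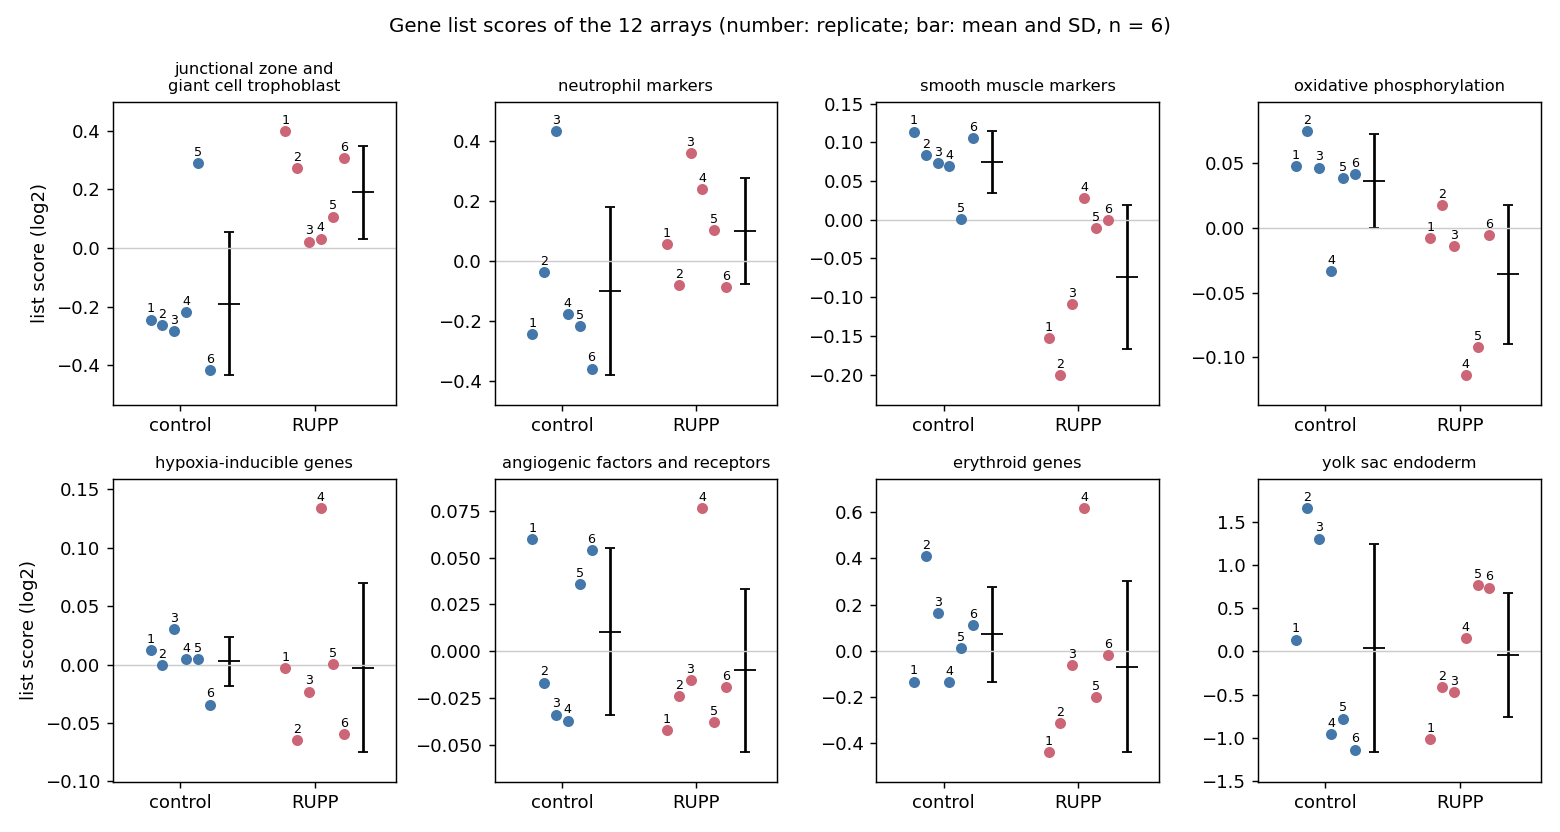
Scores of 8 gene lists (vertical axis, mean log2 deviation of the measured members from their mean over 12 arrays) by group. Each point is 1 array with its replicate number, and bars are mean and SD (n = 6); control 5 lies at 0.29 with the RUPP arrays in the junctional zone panel, and yolk sac scores run from -1.13 to 1.66.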

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

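The tests of a single array, of more blood, of a junctional zone share that raises all members alike, of less uterine wall or decidua, and of other groupings for the count of genes past the adjusted threshold were chosen only after the results were seen.

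In each group of 6 arrays, the log2 levels of named genes and the list scores were examined for an array far from the others of its group. Of 162 such groups, 17 had one, where chance gives about 1 in 20 groups. Control 5 accounted for 6 and RUPP 4 for 4. The groups share the same arrays, and list scores include named genes, so the 17 do not count independent deviations and are not directly comparable with that rate.

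Control 5 stood highest among the controls for Bhlhe41 (log2 level 10.09, next control 9.81), Kcnh1 (7.99, next 7.52), Prl8a5 (12.94, next 12.39) and Prl8a7 (13.12, next 12.55). It also had the highest control score of the unfolded protein response list (0.11) and of the junctional zone and giant cell trophoblast list (0.29, next -0.22). RUPP 4 stood highest among RUPP arrays in the scores of the endothelial list (0.28, next -0.02), the hypoxia-inducible list (0.13) and the angiogenic list (0.077), and for Defa5 (log2 level 7.15, next 6.72).

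Control 3 stood apart for Blvra (8.90, highest control), Edn1 (8.11, lowest control) and the labyrinth trophoblast score (0.060, highest control). Control 6 was highest for Slco4c1 (9.40) and Sod1 (12.34). Control 1 was lowest for Prxl2b (6.79), and control 4 had the lowest control score of oxidative phosphorylation (-0.033, next 0.04).

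The first pattern is the higher junctional zone list in RUPP. No single array carried the difference, of which at least 88.0% remained whichever array was left out. Of 100 splits of the 12 arrays, 1, the real one, gave a mean t of the list as large (2.17, highest other 2.10). The exact permutation p was 0.0130 for this list alone and 0.126 adjusted over 29 lists. The list was picked because the same data called it, which favours a small split count, so chance is not excluded as the source of the difference. A larger share of junctional zone tissue in the RUPP samples may account for it or not: the 94.7% of 19 members above the median level of all genes with a fold change above 0 restates the list's own call and decides nothing, and the intervals of 65.4% of all members (17 of 26) held the list mean of 0.38, which decides neither way. The 9 others included bright genes near the top of the array's scale (Prl3b1 -0.01, Prl2a1 0.05, Prl2b1 0.05, Tpbpa 0.22), Prl7a3 above the mean (1.37), and members well below that top, Hand1 (0.09 at log2 level 12.04), Plac1 (0.04 at 8.21), Ascl2 (-0.11 at 8.2) and Prl2c1 (-0.10 at 6.87), named after their values were seen. Cross-hybridization among paralogs cannot be told apart from a change of many genes. Only 4 members (Ascl2, Hand1, Plac1 and Tpbpa) lie outside the Prl, Psg, Ceacam and granzyme families (median 0.063, standard error 0.068). Regulation by ischemia itself was not separated from tissue share, nor from an effect of surgery, since no operation is given for the controls. It was not separated from a difference in gestational day either, since the controls' day of collection is not given. No test of surgery or gestational day was run for this or the other patterns.

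The second pattern is the higher neutrophil list. At least 73.8% of the difference remained whichever array was left out, so no single array carried most of it. Of 100 splits, 10 gave a mean t as large (1.32, highest other 2.13), so chance cannot be excluded. More blood in the RUPP samples would raise erythroid genes, whose score difference was -0.14 with a standard error of 0.17, too uncertain to decide. An effect of RUPP on neutrophil content may also be present and stays untested.

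The third pattern is the lower smooth muscle and oxidative phosphorylation lists. At least 78.3% of either difference remained whichever array was left out. Of 100 splits, 2 gave as large a mean t for smooth muscle (1.92, highest other 1.99) and 3 for oxidative phosphorylation (1.41, highest other 1.48). Both lists were also picked because the same data called them, so these counts do not exclude chance. Adjusted over 29 lists, neither passed (exact permutation adjusted p = 0.126 and 0.141). One tissue gradient behind both would make their scores vary together within groups, but they correlated at r = -0.55 (permutation p = 0.067; rho = -0.38, permutation p = 0.219; r = -0.19 without the 2 farthest arrays; 1 relation tested). Less uterine wall or decidua in the RUPP samples may contribute to the smooth muscle difference and remains open. The decidual score differed by 0.034 with a standard error of 0.037, and by 0.01 to 0.05 when single arrays were left out (RUPP 4 and control 2). This mean was raised by Prl8a2 (0.63), while the list median was -0.01 and 8 of 14 members were below 0.

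For the 0 genes past the adjusted threshold, a comparison with other splits decides nothing, since all 100 of 100 must give at least 0; the highest other gave 1. At an unadjusted p under 0.05, 3 of 100 splits gave as many as the real 1704, and the highest other gave 2303. Chance is unlikely for this count but not excluded, since another split of the same arrays gave more genes. For the number of gene lists past the camera threshold, 84 of 100 splits gave at least the 4 of the real split and the highest other gave 12, several times the real count, which points to structure among the arrays that is shared by genes of a list and not taken up by the preset correlation.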

How the results depend on the processing

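The values of lists within each series of description numbers, the fits without 3 outlying arrays, with the yolk sac score as covariate, the permutation of list scores and the estimated correlation within each alternative fit were chosen after the data were seen.

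The 0 genes higher in RUPP became 1 (Kcnh1, log2 fold change 0.52) among arrays with description numbers up to 18, and 15 with an unadjusted p and a 1.5-fold difference as the looser criterion. Leaving out each array gave 0 to 15 higher genes, with 15 without control 5, and 0 to 1 lower genes, with 1 without RUPP 6. Under all other alternatives, including both filters, every probe set tested, array weights and an adjusted p of 0.1, both counts stayed at 0. The 2 higher lists became 4 with quantile normalization, 5 above the 25th percentile of level, 9 among description numbers from 19, 7 without the 3 outlying arrays, and 0 with the estimated correlation, fry or exact permutation. The 2 lower lists became 5 with array weights, 6 among description numbers from 19, 4 without the 3 outlying arrays, and 0 with the estimated correlation, fry or exact permutation. Leaving out each array gave 2 to 6 higher and 2 to 5 lower lists. With an estimated correlation in each of the 23 other fits, 0 lists were higher and 0 lower. The fits from 19 rest on 4 arrays, and the estimated correlation allows for genes that vary together. Lists higher from 19 included macrophage markers (0.18), immediate early genes (0.13), complement and coagulation (0.10) and cell cycle (0.05). Lists lower from 19 included cholesterol synthesis (-0.11) and nutrient transporters (-0.08). The cause of the other changes was not tested.

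No called list changed direction. The 24 genes with the smallest p kept their sign in all their alternatives. For the dim genes Igbp1b, Ube2t, Polr1has, Plcd4, Cxcr6 and Ptpro these did not include the level filters, which removed them. They had 24 alternatives each, against 26 for Bhlhe41. Of 1317 values of 52 named genes under alternatives, 7 passed the threshold and 35 changed sign, those of Flt1, Eng, Vegfa, Edn1, Il6, Sod1 and Nos3. The 25 lists not called gave 673 values, 62 of them past the threshold, with 49 changes of sign. Replicate numbers are shared by both groups but do not pair the samples: same-numbered arrays correlated at -0.31 to 0.06, and only control 1 correlated best with its own number. With the replicate block, 0 genes were higher and 0 lower, and the macrophage and cholesterol synthesis lists passed in addition. A log2 offset for linear values was not run, since the values are on a log scale. How far signal over background limits dim genes was not measured, as no background values were used here.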

Other observations

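Among the 29 lists, scores of yolk sac endoderm genes varied most between arrays, with no group difference past the test over all 12 arrays (-0.08), although the difference was 0.60 without the 3 outlying arrays and 0.25 among description numbers from 19, both lost with an estimated correlation (adjusted p = 0.463 and 0.509). Ttr, the thyroid hormone carrier transthyretin, ranged from a log2 level of 7.42 to 13.2 over the 12 arrays, a 56.4-fold range. Afp, alpha-fetoprotein, ranged over 50.7-fold and Apob, the lipoprotein gene, over 44.7-fold. The transferrin gene Tf spanned 24.5-fold and Cubn, an endocytic receptor of the visceral yolk sac, 13.1-fold. Of the 20 measured members, 19 correlated with the mean of the other members at r of at least 0.5 after removal of group means, the exception being albumin, Alb (r = -0.21). Ttr, Afp, Apob, Tf and Alb were chosen after their values were seen. Control 2 and control 3 had the highest scores (1.66 and 1.30) and lay farthest out on the first principal component, which held 26.4% of the variance, while control 6 (-1.13) and RUPP 1 (-1.01) had the lowest scores.

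RUPP 4 lay farthest out on the second principal component (16.1% of the variance) and had the highest scores of all 12 arrays for erythroid genes (0.62), endothelial markers (0.28), complement and coagulation (0.18) and decidual stroma (0.14), with the lowest for labyrinth trophoblast (-0.12) and oxidative phosphorylation (-0.11).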
